A study of Mus musculus with 6 samples.

How the data were processed

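Total RNA was measured on Affymetrix 3 prime expression arrays from mouse (C57BL/6J) bone marrow c-Kit+Sca-1+Lin- cells, called KSL cells, the gate that holds blood stem and early progenitor cells. Per the labels, the cells had been cultured for 7 days on human umbilical vein endothelial cells in serum-free medium with 5 types of mouse cytokines, with PBS or mD1R added, and were sorted again as KSL cells before Trizol extraction and biotin labelling. There were 6 arrays, 3 biological replicates with PBS and 3 with mD1R. The labels do not spell out mD1R. It is known from the study as a recombinant protein that carries the receptor-binding domain of the mouse Notch ligand Delta-like 1 and a motif that targets it to endothelium.

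The values the authors deposited are log2 signals for 45101 probe sets, of which 64 are control probe sets. The submitters' processing notes name MAS5 with no version. On the linear scale every array had a 2% trimmed mean of 500, so each array had been scaled on its own. Linear values under 1 were listed as log2 0, which was the case for 239 to 422 values per array. Detection calls were not used here, so a low signal cannot be told from background. MAS5 subtracts mismatch signals, which makes low values noisy, and fold changes of genes that are dim in one group are therefore imprecise. Of the probe sets, 34958 carried 1 gene symbol in the platform annotation and 932 carried several and were not named. Another 9160 probe sets other than controls were not listed there and stayed unnamed. The Entrez IDs of 34754 probe sets were found in the RefSeq gene table, and 0 symbols changed.

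The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with a variance trend, two-sided) on the log2 values as deposited, with no further scaling, pseudocount or block. Probe sets with a mean log2 signal below the 40th percentile, 5.27, were left out, which kept 27022. P-values were adjusted by the Benjamini-Hochberg method and the threshold was 0.05. A gene was represented by its brightest kept probe set with 1 symbol, which gave 12320 genes. Errors of log2 changes are limma's standard errors, with n = 3 per group. The number of arrays limits the precision, and the median standard error of a log2 change was 0.31.

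Gene lists were tested with limma's camera, with a preset correlation between genes of 0.01 and also with the correlation estimated from the arrays. There were 35 lists, fixed before the data were examined, with 733 of their 872 genes measured. They cover Notch signalling, blood stem and progenitor cells, other cell types the gate could hold, and cell cycle, stress, signalling and metabolic genes. The genes named were fixed by rule at the same time. The rule took the 12 largest rises and 12 largest falls among genes past the threshold whose groups did not overlap, passing over unnamed transcripts. It also took up to 4 members per list by smallest p among those past the threshold adjusted over the list alone (otherwise the 2 with the smallest p), a fixed set of Notch, stem cell and lineage genes, and the markers of the gate. Genes outside the rule are said to have been chosen after their values were seen.

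The test was run on simulated data drawn from the real means and spreads, with 200 of the 27022 probe sets changed, in 10 simulations. It recovered 6.8% of changes of 1 on the log2 scale and 64.5% of changes of 2. Of its calls, 7.76% were false, above the nominal share. A list moved by 0.5 was found in 10 of 10 simulations, and 3 unmoved lists were called over all simulations of 35 lists each. The simulated genes vary independently, so this says nothing about lists whose genes vary together. In the real data 12.6% of probe sets passed the threshold, far more than were changed in the simulations. Recovery depends on that share, so the recovered percentages may not hold for the real data.

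The arrays were searched for batches. The BioB hybridisation control, relative to the BioC, BioD and cre controls, split them into 2 sets that do not follow the groups. PBS replicate 1 and mD1R replicates 1 and 2 lay between -3.51 and -3.35 (log2), and PBS replicates 2 and 3 and mD1R replicate 3 between -5.98 and -5.84. These sets are called spike-in batches below, and the split was found after seeing the data. Each change within a batch rests on a single array of 1 group, PBS replicate 1 in the first set and mD1R replicate 3 in the second. Alternatives covered the scaling between arrays, a pseudocount, the filter, the variance model, array weights, the replicate number or the spike-in batch as a block, ambiguous probe sets, the threshold and leaving out each array in turn.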

Results

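The data are 6 arrays of KSL cells sorted after 7 days of culture on endothelial cells, 3 with PBS and 3 with mD1R. The comparison asks how exposure to this Notch ligand protein changed gene expression in cells that still carried the KSL surface markers. Array medians of log2 signal lay between 6.07 and 6.42. No 2 arrays of a group shared identical nonzero values, and the SD of their log2 differences lay between 0.504 and 0.960. Arrays of the same group correlated more closely (mean Pearson r 0.945 across kept probe sets) than arrays of different groups (0.886). The difference of 0.0589 had an exact permutation p of 0.1, the smallest that 3 against 3 arrays can give. On the first principal component, which held 56.9% of the variance, the PBS arrays lay at -64.5, -70.7 and -79.4 and mD1R replicates 1 and 2 at 108.4 and 93.6. Replicate 3 of mD1R lay between them, at 12.6.

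The genes of the gate came first. Kit, the receptor for stem cell factor, had log2 signals of 9.34 ± 0.57 (SD, n = 3) with PBS and 10.69 ± 0.97 with mD1R, a difference that did not pass (adjusted p = 0.109). Ptprc, the pan-leukocyte antigen, differed by -0.34 ± 0.21 (SE) and Itgam, a myeloid antigen, by -0.33 ± 0.22. Cd3e differed by -1.41 ± 0.59 and Cd8a by -0.40 ± 0.53, and none of these passed. A second Ptprc probe set gave -1.89 and passed. Cd4 lay below the filter. Ly6a, which encodes Sca-1, and Ly6g were not analysed here because they had no kept probe set with a single symbol.

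With mD1R, mast cell and basophil genes rose and mitosis genes fell (adjusted p = 0.360 and 0.445 with an estimated correlation, so neither list passed that test). Of 27022 probe sets, 3413 passed adjusted p 0.05, 1657 higher and 1756 lower with mD1R. Among 12320 named genes, 1046 were higher and 873 lower. The groups did not overlap in 36.0% of probe sets, against 10% by chance. At unadjusted p 0.05 and at least 2-fold, 2170 probe sets were higher and 2321 lower. The count past adjusted p 0.05 changed strongly when 1 array was left out, which also lowers the precision. It was 0 in limma without PBS replicate 3, where 5853 probe sets had an unadjusted p under 0.05. In that setting 4007 were past unadjusted p 0.05 and 2-fold, against 4491 with all arrays. The count past adjusted p 0.05 was 1294 without PBS replicate 1 and 544 without PBS replicate 2. Without mD1R replicates 1, 2 and 3 it was 2192, 723 and 5565. Counts of list members that rose or fell, given below for such settings, are counts past the adjusted threshold. Without PBS replicate 3 they are therefore 0 for every list, whatever the size of the changes. Of the genes named here, 103 lost their call without PBS replicate 3, 60 without PBS replicate 2, 50 without mD1R replicate 2 and 41 without PBS replicate 1. With the spike-in batch as a block the count was 3452. Over all kept probe sets the log2 changes within the 2 batches correlated at 0.57.

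The largest rise was in the mast cell protease pseudogene Mcpt-ps1, by 6.49 ± 0.67 (log2, SE). The 12 largest also held mast cell protease genes, of which Mcpt4 rose by 4.94 ± 1.08, Mcpt2 by 4.69 ± 0.88, Tpsg1 by 4.41 ± 0.48 and Mcpt1 by 4.18 ± 0.92. The others were C1s1 (5.23), Speg (4.74), the macrophage metalloelastase Mmp12 (4.56), Fstl1 (4.47), Cyp1b1 (4.43), the growth factor Igf1 (4.30) and Atp6v0d2 (4.26). The largest falls were in Slc4a1, the red cell anion exchanger (-5.72 ± 1.45), Ncam1 (-5.61 ± 1.05), Slco4c1 (-5.53), Scrg1 (-5.30), Asprv1 (-5.20), Itgb2l (-5.13), Ppp1r42 (-5.13), the natural killer receptor gene Klra7 (-5.01), Aplnr (-4.98), Fcnb (-4.97), Rflnb (-4.80) and Pglyrp1 (-4.76). Several of these genes were near the lower end of the signal range in one group, so the size of their change, and with it their order, is imprecise.

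Mast cell and basophil genes were the list that rose most. Of 22 measured members, 17 rose and 0 fell over all genes tested, and 20 rose and 1 fell adjusted over the list alone. The median log2 change was 2.39 (camera adjusted p = 1.12e-09, adjusted p = 0.360 with an estimated correlation), with medians of 1.79 and 2.53 within the 2 spike-in batches. Cpa3, a mast cell carboxypeptidase, rose by 2.78 ± 0.26, the receptor chain gene Csf2rb2 by 2.35 ± 0.21, Cyp11a1 by 3.41 ± 0.33 and the amine transporter Slc18a2 by 2.34 ± 0.24. Leaving out PBS replicates 1, 2 and 3 in turn, 13, 8 and 0 members passed as higher. Leaving out mD1R replicates 1, 2 and 3, 14, 10 and 18 did, with 1 passing as lower in the last case. The list itself passed with the preset correlation in all 19 settings, with medians between 2.12 and 2.63. The array of mD1R replicate 3 had Mcpt4 at 6.04, against 8.64 and 10.30 in the other mD1R arrays, and Cpa3 at 14.61, against 14.34 and 14.40.

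All 34 measured mitosis genes fell, with a median log2 change of -1.90 (camera adjusted p = 2.19e-24, adjusted p = 0.445 with an estimated correlation). The medians within the spike-in batches were -2.35 and -1.14. Kif23, a kinesin of cell division, fell from 11.14 ± 0.24 (log2 signal, SD) to 9.14 ± 0.17. Cdca3 fell by 2.28 ± 0.24, the survivin gene Birc5 by 2.20 ± 0.24 and the centromere histone gene Cenpa by 1.83 ± 0.22. Leaving out PBS replicates 1, 2 and 3 in turn, 19, 18 and 0 of the 34 passed as lower, and leaving out mD1R replicates 1, 2 and 3, 32, 20 and 34 did. The list's median lay between -2.24 and -1.73 in all 19 settings and the list passed with the preset correlation in each. Of 34 DNA replication genes, 19 fell over all genes tested and 27 adjusted over the list alone, with a median of -1.12 (adjusted p = 1.55e-12, adjusted p = 0.589 with an estimated correlation) and batch medians of -1.81 and -0.60. Of these, 12 fell with no variance trend, 3, 2 and 0 without PBS replicates 1, 2 and 3, and 13, 5 and 27 without mD1R replicates 1, 2 and 3. E2f8 fell by 2.34 ± 0.34, Cdc45 by 1.92 ± 0.31, and Mcm5 by 1.99 ± 0.33. Rrm1 fell from a log2 signal of 11.88 ± 0.15 (SD) to 10.38 ± 0.49. A second probe set of Cdc45 gave 0.05 and one of Cdca3 -0.33, and neither passed. Among 25 cyclin-dependent kinase inhibitor and quiescence genes, 7 fell and 1 rose (9 and 2 adjusted over the list alone). Cdkn2c (-1.66 ± 0.26), Cdkn1b (-1.42 ± 0.36), Klf4 (-2.01 ± 0.33), Nr4a1 (-3.40 ± 0.60) and Rbl1 (-1.04 ± 0.19) fell, whereas Cdkn1a rose by 1.65 ± 0.34. Cdkn1c differed by 1.57 ± 0.68 and did not pass (adjusted p = 0.167). The list's adjusted p was 0.0305, 0.641 with an estimated correlation, 0.0983 with the spike-in batch as a block and 0.0593 without mD1R replicate 1, and the batch medians were -0.12 and -0.08. Members that fell numbered 4, 1 and 0 without PBS replicates 1, 2 and 3, and without mD1R replicate 2, 3 fell.

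**Figure D1:**
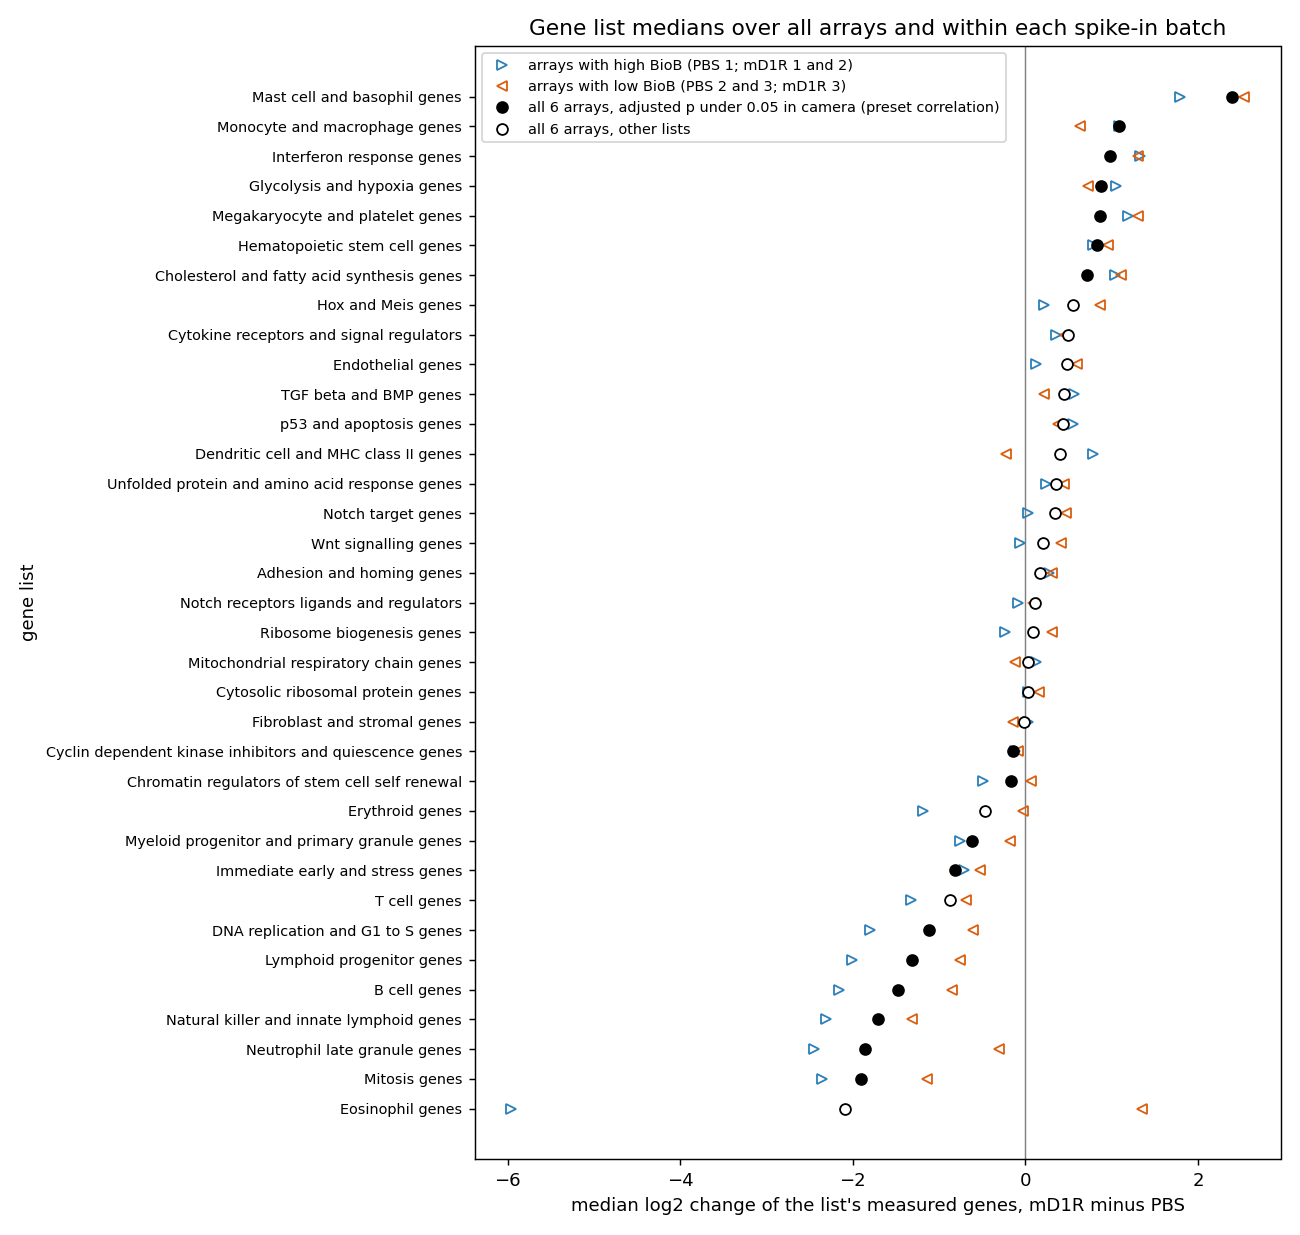
Median log2 change (mD1R minus PBS, horizontal axis) of the measured genes of each of the 35 gene lists (vertical axis), over all 6 arrays (circles, filled where camera with the preset correlation passed adjusted p 0.05) and within each spike-in batch (triangles). The mast cell and basophil list has the highest median, 2.39, and the eosinophil list, at -2.09, has batch medians of -5.96 and 1.35.

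The Notch target list did not pass, which does not show that no shift took place. Of its 20 genes, 14 were measured. Ptcra lay below the filter, and Tcf7 had no kept probe set with a single symbol. The median log2 change of 14 measured members was 0.34 and the mean -0.06 (adjusted p = 0.784, direction higher), so median and mean differed in sign. Cdkn1a rose, while the lymphoid genes Cd7 (-3.88 ± 0.44) and Cd3g (-1.80 ± 0.34) fell. The transcriptional repressor gene Hes1 differed by 0.09 ± 0.24, Hey1 by 0.56 ± 0.46, Dtx1 by 0.33 ± 0.37, Nrarp by -0.33 ± 0.40, Notch1 by 0.16 ± 0.18, Myc by 0.41 ± 0.32, Gata3 by -1.12 ± 0.76 and Il2ra by 1.32 ± 0.47, and none of these passed. A second Notch1 probe set gave -0.40. Of 31 Notch receptors, ligands and regulators, 4 rose and 0 fell (adjusted p of the list 0.780). They were the ligand gene Jag1 (2.13 ± 0.26), Dtx3 (1.19 ± 0.20), the sheddase gene Adam17 (1.36 ± 0.24) and Psen2 (1.30 ± 0.25). A second Psen2 probe set gave 0.15 and did not pass.

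Hematopoietic stem cell genes were higher as a list, with a median of 0.83 over 38 members (adjusted p = 0.0112, adjusted p = 0.445 with an estimated correlation) and batch medians of 0.78 and 0.96. Of these, 6 rose and 1 fell over all genes tested, and 9 rose and 2 fell adjusted over the list alone. With the spike-in batch as a block 14 rose and 1 fell. Without PBS replicates 2 and 3, 2 and 0 rose, and without mD1R replicate 2, 3 rose. The list no longer passed without mD1R replicate 3 (median 0.57, adjusted p = 0.0576). The transcription factor gene Gata2, which is also on the mast cell and basophil list, rose by 2.22 ± 0.30, the stem cell marker gene Procr by 3.01 ± 0.42 and Tal1 by 1.37 ± 0.22, while Erg fell by 1.27 ± 0.25. Hoxb4 differed by 0.56 ± 0.25 (a second probe set gave -0.06) and Bmi1 by 0.24 ± 0.36, and neither passed. The Hox and Meis list did not pass (adjusted p = 0.360). Chromatin regulators of self renewal were lower as a list (5 of 27 fell, median -0.17, adjusted p = 0.0303, adjusted p = 0.641 with an estimated correlation), with falls in Satb1 (-1.99 ± 0.29), Ezh2 (-1.39 ± 0.25), Asxl1 (-1.42 ± 0.25) and Sirt1 (-0.79 ± 0.20). The 5 falls also passed adjusted over the list alone. Its medians within the spike-in batches, each with a single array of 1 group, were -0.49 and 0.06, so the median was not lower in both. The chromatin list did not pass without PBS replicate 1, mD1R replicate 1 or mD1R replicate 2 (adjusted p = 0.0542, 0.0795 and 0.0648), or with the filter at the 60th percentile (0.0656). Of its genes, 3, 2 and 0 fell without PBS replicates 1, 2 and 3, and without mD1R replicate 2, 1 fell.

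Among genes of mature myeloid cells, neutrophil late granule genes were lower. Of 22 members, 4 fell and 0 rose over all genes tested and 5 fell adjusted over the list alone (median -1.85, adjusted p = 0.000245, adjusted p = 0.652 with an estimated correlation). The list's medians were -2.45 and -0.30 within the spike-in batches. The falling genes were Fcnb, Pglyrp1, Itgb2l and the gelatinase gene Mmp9 (-4.38 ± 1.13). Of the list, 12 fell without mD1R replicate 3 or with array weights, 9 with the replicate number as a block, 1 with no variance trend, with robust variance or without mD1R replicate 1, and 0 without mD1R replicate 2 or any one PBS replicate. Mpo, the neutrophil primary granule peroxidase, had a log2 signal of 14.46 ± 0.18 (SD) with PBS, and of 7.39, 9.77 and 13.93 in mD1R replicates 1, 2 and 3, and did not pass (adjusted p = 0.0876). The myeloid progenitor and primary granule list was lower by its test (median -0.62, batch medians -0.76 and -0.18, adjusted p = 0.0303, adjusted p = 0.641 with an estimated correlation). Of its 21 members 1 rose, Csf1r (1.09 ± 0.24), and 0 fell over all genes tested, against 3 and 6 adjusted over the list alone. These counts turned on the setting, with 3 rising and 8 falling with array weights, 1 and 8 without mD1R replicate 3, 1 and 6 with the replicate number as a block, 0 and 2 with arrays centred on their medians, and 0 and 0 with no variance trend, without mD1R replicate 2 or without any one PBS replicate. It did not pass without mD1R replicate 1 or 2 (adjusted p = 0.0754 and 0.0664).

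Monocyte and macrophage genes were higher, with 10 of 24 members rising and 0 falling (10 and 1 adjusted over the list alone; median 1.09, adjusted p = 0.00138, adjusted p = 0.445 with an estimated correlation) and batch medians of 1.08 and 0.64. The risers were 6, 4 and 0 without PBS replicates 1, 2 and 3, and without mD1R replicate 2, 4 rose. Ms4a7 rose by 2.15 ± 0.21, the chemokine gene Ccl9 by 1.41 ± 0.19, the scavenger receptor gene Msr1 by 2.29 ± 0.31 and Cd68 by 1.74 ± 0.27. Megakaryocyte and platelet genes were higher (5 of 24 rose and 0 fell, 10 and 1 adjusted over the list alone; median 0.86, adjusted p = 0.00689, adjusted p = 0.673 with an estimated correlation), including the platelet chemokine gene Pf4 (1.92 ± 0.26), Gp9 (1.64 ± 0.28), Plek (0.86 ± 0.19) and Rab27b (2.20 ± 0.49). With the spike-in batch as a block 13 of them rose. Platelet genes that rose numbered 3, 3 and 0 without PBS replicates 1, 2 and 3, 1 without mD1R replicate 2 and 2 with no variance trend. The list's batch medians were 1.19 and 1.30, and it did not pass with array weights (adjusted p = 0.0660), without PBS replicate 1 (0.0640) or without mD1R replicate 3 (0.171). The eosinophil list of 6 genes (adjusted p = 0.0503), the erythroid list (0.221), the dendritic cell list (0.299), the endothelial list (0.455) and the fibroblast list (0.642) did not pass. The eosinophil call turned on the setting, since that list passed in the lower direction in 8 of 16 settings, among them no filter (adjusted p = 0.0102), and its batch medians differed in sign.

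Lymphoid genes were lower. Among 19 lymphoid progenitor genes 7 fell and 1 rose over all genes tested, and 15 fell and 1 rose adjusted over the list alone (median -1.32, adjusted p = 1.83e-05, adjusted p = 0.445 with an estimated correlation), with batch medians of -2.01 and -0.76. When PBS replicates 1, 2 and 3 were left out in turn, 4, 3 and 0 of these genes fell. Dntt, which encodes the terminal transferase of antigen receptor rearrangement, fell by 3.42 ± 0.46, the B lineage factor gene Ebf1 by 2.92 ± 0.39, and the cytokine receptor gene Flt3 by 2.08 ± 0.52. Ikzf1 fell 2.83-fold. Of 16 B cell genes 6 fell (9 adjusted over the list alone; median -1.48, adjusted p = 0.000302, 0.445 with an estimated correlation), among them Bank1 (-2.50 ± 0.26), Blk (-1.62 ± 0.31) and Igll1 (-3.09 ± 0.64), with batch medians of -2.16 and -0.86. B cell genes that fell numbered 2, 2 and 0 without PBS replicates 1, 2 and 3. Of 13 natural killer and innate lymphoid genes 6 fell and 1 rose (10 and 2 adjusted over the list alone; median -1.70, adjusted p = 0.000606, adjusted p = 0.445 with an estimated correlation), with batch medians of -2.31 and -1.32. Klrd1 (-2.22 ± 0.40), Il2rb (-2.22 ± 0.42), Ncr1 (-2.35 ± 0.47) and Eomes (-1.82 ± 0.38) fell. In this list 1, 0 and 0 fell without PBS replicates 1, 2 and 3, and without mD1R replicates 1 and 2, 4 and 1. The natural killer list did not pass with the filter at the 60th percentile, where 8 genes were measured (adjusted p = 0.0729). The T cell list did not pass (adjusted p = 0.0796), although Cd3d fell by 3.73 ± 0.34 and Cd2 by 1.95 ± 0.38, while Lat rose by 1.53 ± 0.25.

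**Figure D2:**
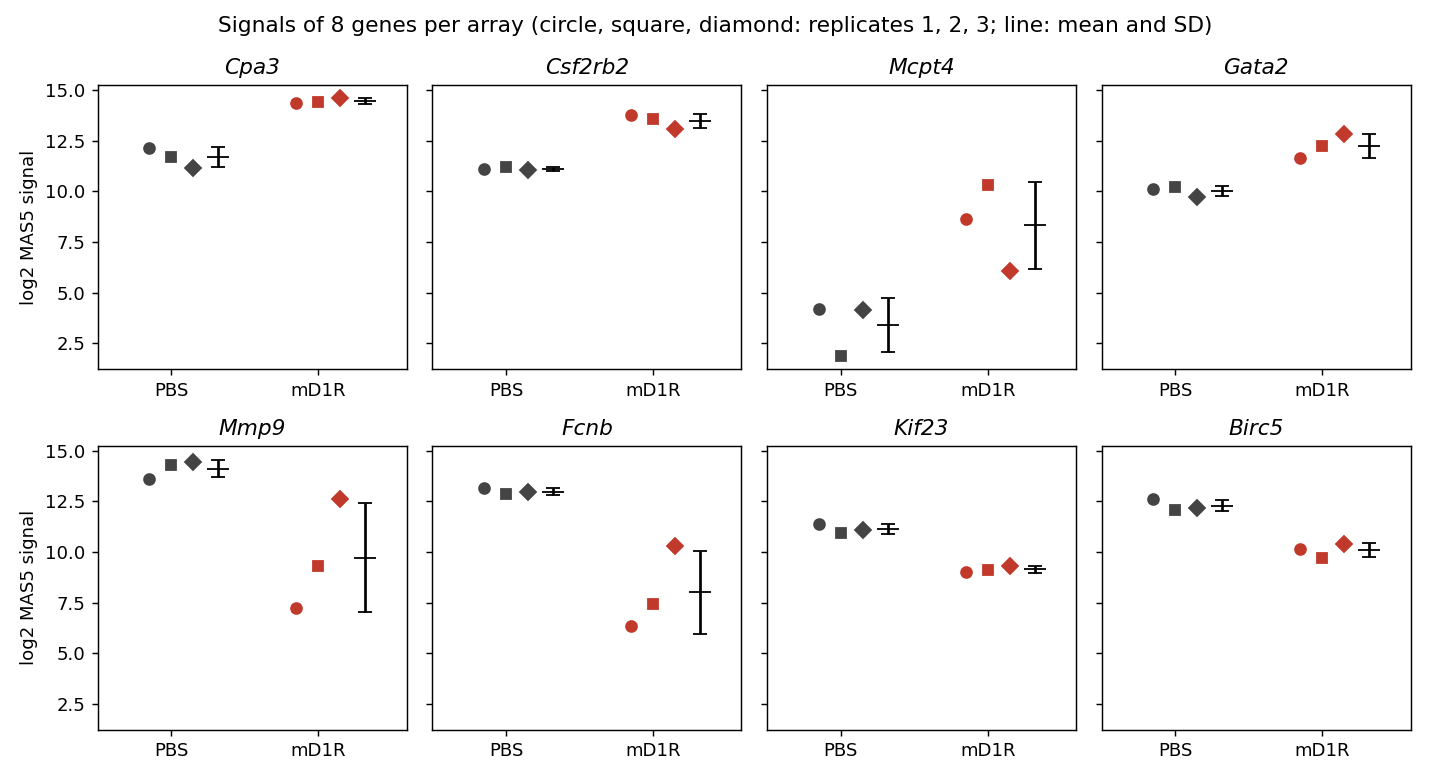
Log2 MAS5 signal (vertical axis) of 8 genes in each PBS and mD1R array (horizontal axis), with symbols for replicates 1, 2 and 3 and a line for the mean and SD of each group. In mD1R replicate 3, Mmp9 lies at 12.63, nearer to the PBS arrays than replicates 1 and 2 do at 7.25 and 9.30, while Gata2 lies at 12.84, above the other mD1R arrays.

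Interferon response genes were higher, with 8 of 31 rising and 0 falling over all genes tested, 17 adjusted over the list alone, 24 with the spike-in batch as a block and 4 with arrays centred on their medians (median 0.98, adjusted p = 5.28e-06, adjusted p = 0.641 with an estimated correlation). The batch medians were 1.33 and 1.30. Interferon genes that rose numbered 2, 2 and 0 without PBS replicates 1, 2 and 3, without mD1R replicate 2, 3 rose, and with no variance trend 3 rose. Irgm1 rose by 1.31 ± 0.18, Bst2 by 1.75 ± 0.25, Ifi204 by 1.21 ± 0.26 and Stat2 by 1.23 ± 0.27. Immediate early genes were lower (8 of 25 fell and 1 rose, 12 and 4 adjusted over the list alone; median -0.82, adjusted p = 0.00251, adjusted p = 0.641 with an estimated correlation), including Jun (-1.45 ± 0.25), Fosb (-2.50 ± 0.49) and Ier2 (-1.74 ± 0.34), with batch medians of -0.71 and -0.52. A second Jun probe set gave -0.03 and did not pass. Immediate early genes that fell numbered 4, 0 and 0 without PBS replicates 1, 2 and 3, and without mD1R replicate 2, 4 fell. Cholesterol and fatty acid synthesis genes were higher (6 of 22 rose, 8 adjusted over the list alone and 14 with the spike-in batch as a block; median 0.71, adjusted p = 0.000196, adjusted p = 0.641 with an estimated correlation). Dhcr7 rose by 1.81 ± 0.22, the desaturase gene Scd1 by 2.09 ± 0.32, Lss by 1.45 ± 0.25 and Sqle by 1.63 ± 0.31, with batch medians of 1.04 and 1.10. Without PBS replicate 3, 0 of them rose, and without mD1R replicate 2, 3 rose. Glycolysis and hypoxia genes were higher (3 of 22 rose, 4 adjusted over the list alone; median 0.87, adjusted p = 0.00352, adjusted p = 0.673 with an estimated correlation), with rises in P4ha1 (2.03 ± 0.31), Car9 (1.47 ± 0.29) and Pfkp (0.90 ± 0.21) and batch medians of 1.05 and 0.73. That list did not pass without PBS replicate 1 (adjusted p = 0.0504) or mD1R replicate 2 (0.0528), and 10 of its genes rose without mD1R replicate 1, 1 without mD1R replicate 2 or PBS replicate 2 and 0 without PBS replicate 3.

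The remaining lists did not pass. They were p53 and apoptosis genes (adjusted p = 0.0635, with rises in Phlda3, Zmat3 and Ccng1 of 1.89, 1.76 and 1.21), cytokine receptors (0.110, with Il1r1 up by 2.23 ± 0.37 and Il6ra down, -2.05 ± 0.26), adhesion and homing genes (0.607, where the chemokine receptor gene Cxcr4 fell by 1.14 ± 0.25), Wnt genes (0.396), TGF beta and BMP genes (0.572) and unfolded protein response genes (0.360). Members of the last 3 of these lists moved both ways. In the Wnt list 4 rose and 2 fell, among them Fzd7 (2.37) and Lef1 (-2.52). For TGF beta and BMP genes 1 rose and 3 fell, among them Acvr1 (1.77) and Id3 (-1.82). Of the unfolded protein response genes 5 rose and 1 fell. The p53 call turned on the setting. That list passed in the higher direction in 6 of 19 settings, among them without PBS replicate 2 (adjusted p = 0.0185). No member passed among 31 respiratory chain genes (median 0.03, adjusted p = 0.784), 25 ribosome biogenesis genes (0.09, 0.847) or 25 ribosomal protein genes (0.03, 0.784). Without mD1R replicate 1 the ribosomal protein list passed as higher (median 0.20, adjusted p = 0.0317). The signs of the medians of these 3 lists were opposite to the direction of their tests. Other probe sets of some named genes changed less. For each gene, the value nearest to 0 was -1.67 for Aplnr, 2.12 for Speg, 1.18 for Cyp11a1, -0.48 for Asxl1, -0.62 for Ikzf1, 0.43 for Rab27b and 0.55 for Pfkp, whose other probe sets did not pass, and 0.39 for Jag1, where 1 of 2 others passed. In all, 17 of 35 lists passed with the preset correlation, 7 higher and 10 lower, and 0 passed with an estimated correlation. Other splits of the same 6 arrays into 3 and 3 gave 6 to 17 lists with the preset correlation. Under the estimated correlation the mast cell and basophil list had an unadjusted p of 0.0103.

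RNA quality was compared through the control probe sets. The 3 prime signal of Actb exceeded its 5 prime signal by 0.242 ± 0.034 (log2, SD, n = 3) with PBS and by 0.418 ± 0.043 with mD1R, with no overlap between groups (two-sided exact permutation p = 0.1, the smallest possible, and 0.2 adjusted over 4 measures). For Gapdh the 2 groups differed by 0.06 (exact permutation p = 0.5). The Actb ratio separated the groups, so its effect is hard to tell from that of mD1R, and no adjustment for it was run.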

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

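The tests of the 3 patterns below were chosen after the values had been seen. The counts over other splits of the arrays were planned.

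Outside the tested probe sets, 3 measures were higher in every mD1R array than in any PBS array, 1 control signal and 2 differences between Actb probe sets. Of 19 mouse control probe sets, 1 was higher in this way, the B1 repeat (by 0.82 on the log2 scale), and 1 was lower in every mD1R array, the 3 prime probe set of the transferrin receptor (-0.81), against the 10% of measures that separate either way by chance, so these 2 are no sign of a shift of the controls. The Actb 3 prime to 5 prime difference was larger by 0.18 and the Actb 3 prime to middle difference also by 0.18.

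The 6 arrays can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 3413 probe sets past adjusted p 0.05 (1 of 10 splits gave as many) and the highest other gave 0. At unadjusted p 0.05 and 2-fold it gave 4491 (1 of 10 splits) and the highest other 1258, which was the split along the spike-in batches. For gene lists the real split gave 17, and so did the highest other, with 3 of 10 splits giving as many, the real one included, and the remaining splits between 6 and 16. The count of lists by itself does not set the real split apart from the others.

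Mast cell and basophil genes were higher with mD1R. Within the 2 spike-in batches the list medians were 1.79 and 2.53, which argues against the hybridisation batch as the whole cause, though each rests on a single array of one group. More mast cells or basophils in the sorted gate could give this pattern, as could a change inside the sorted cells. Of 10 members with a mean log2 signal of 12 or more in the mD1R arrays, 8 rose and 0 fell, which both readings predict, so they cannot be told apart without counts of cells. The exposure to mD1R itself stays open.

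Mitosis genes were lower with mD1R. The batch medians nearest to and farthest from 0 were -1.14 and -2.35, which argues against the hybridisation batch as the whole cause, though each rests on a single array of one group. Dilution by cells that do not divide may contribute. The mitosis median lay below the DNA replication median by 0.79 (difference -0.79), but non-dividing cells that keep some replication transcripts would give that too, so slower division and dilution cannot be told apart here.

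The third pattern is that mD1R replicate 3 lies between the PBS arrays and the other mD1R arrays. A batch shift is argued against for the first principal component only, where PBS replicate 1 lay apart from PBS replicates 2 and 3 by 10.6 and mD1R replicates 1 and 2 from replicate 3 by 88.3. For the granule genes alone the values were -0.43 and -1.54, which leaves a part from the batch open. On the second component (17.4% of the variance) PBS replicates 1, 2 and 3 lay at 60.2, -13.6 and -13.9. There mD1R replicates 1, 2 and 3 lay at 55.4, -37.9 and -50.2. Replicate 2 of mD1R shares its spike-in batch with replicate 1 but lay near replicate 3. This component thus did not follow the spike-in batches, and it set replicate 1 of both groups apart from the other arrays. A batch shift outside the first component is still not excluded. One mast cell or basophil population of fixed makeup is argued against, because 9 of 22 list members lay at least 0.5 above the mean of the other mD1R arrays and 10 at least 0.5 below. The counts alone are weak evidence, since the SD of log2 differences between mD1R arrays was 0.787 to 0.960. The deviations ran from -3.70 for Mcpt1 to 2.18 for Hdc. Another reading is a mixture, in one share, of RNA from PBS-type cells and from cells like the other mD1R arrays. The positions of 2 lists, chosen after the values had been seen, go against it as the whole cause but do not settle it. Between PBS (0) and the other mD1R arrays (1) mitosis genes lay at a median of 0.765 (quartiles 0.684 and 0.808). The 9 genes of the myeloid progenitor and primary granule list that passed at 2-fold without mD1R replicate 3 lay at 0.458 (0.319 and 0.474). They include the receptor gene Csf1r, which rose and gave the median. These ranges did not overlap in 8 of 8 choices of the arrays taken as the 2 ends. All these choices used the same single array of mD1R replicate 3 and the same genes, so they are not independent. In 1 of them the spike-in shift of the PBS arrays was taken off. Interferon and cholesterol genes, with 5 genes each, lay at 1.53 and 1.18, above what a mixture allows, but at 0.748 and 0.877 with that shift taken off, so they do not decide. Such a mixture may still contribute, and that stays open. The median positions of the mast cell and late granule genes were 0.687 and 0.321, a difference of 0.37 (permutation p = 0.421), which does not decide. With the spike-in shift taken off they were 1.16 and 0.432. The quartiles of the mast cell genes were 0.200 and 2.06, or 0.419 and 2.44 with the shift taken off. Their upper quartile thus lay above what a mixture allows in both versions. A wrong label was not tested.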

How the results depend on the processing

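The spike-in batch block was added after seeing the data. All other settings were planned. The count of 3413 probe sets changed by over 1.5 times with no variance trend (2213), array weights (6508) and adjusted p 0.10 (5737), and it ranged from 0 to 5565 when 1 array was left out. The cause was not tested, except that the looser threshold passes more by construction. The count at 2-fold stayed within 1.5 times in all 19 settings. The count of 17 lists became 0 with an estimated correlation. Among lists that had not passed, the eosinophil list passed in 8 of 16 settings, p53 in 6 of 19, T cell in 2 of 18, erythroid and dendritic cell in 2 of 19 each, cytokine receptors in 1 of 19 and, against its direction over all arrays, ribosomal proteins in 1 of 19. The Hematopoietic stem cell list (median 0.83) lost its call with an estimated correlation (adjusted p = 0.445) and without mD1R replicate 3 (0.57), and its medians without 1 array ranged from 0.57 to 0.97. The Notch target list, which passed in no setting run, turned to the lower direction with no filter (median 0.17) and without Myc, Ccnd1, Cdkn1a and Nfkb2 (median 0.12). The Gapdh 3 prime difference became -0.013 with the middle probe set. With the replicate block the count was 4619, and 4384 with quantile normalization added. Deviations of same-numbered arrays correlated at 0.31, 0.03 and 0.13, and not every array correlated best with its own number. So few arrays cannot tell whether the numbers pair the samples, and the main fit took them as unpaired. Among named genes that had not passed, the sign turned for Bmi1 with the spike-in batch block (-0.00079), and without 1 array Bmi1 ranged from -0.18 to 0.54, Cd8a from -0.79 to 0.18 and Hes1 from -0.071 to 0.19. Depth has no counterpart here: signal over background was not used, so low signals limit what can be said of dim genes.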

Other observations

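Gene families were formed from symbol stems, with at least 8 measured genes each. Whether any family shifted as a whole was planned before the families were looked at. Of 197 families, 6 passed adjusted p 0.05 in camera with the preset correlation, and 0 with an estimated correlation. The same 10 splits of the arrays gave up to 9 families, and the split along the spike-in batches gave 6, so the count is no sign of a shared change of gene families with mD1R. The family with the smallest p was the aldo-keto reductases (stem Akr), enzymes that reduce aldehydes and ketones, where 5 of 8 members rose and 0 fell. Akr1c12 rose by 2.89 ± 0.39 (log2, SE), Akr1b8 by 2.65 ± 0.28, Akr1c18 by 2.54 ± 0.56 and Akr1c13 by 2.47 ± 0.37. These genes were chosen after their values were seen, and near-identical members can share probe signal.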
